A study of Homo sapiens with 507 samples.

How the data were processed

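The 507 arrays came from 59 established human tumour cell lines of the NCI-60 panel, with 9 tissues of origin, exposed to sirolimus at 10 or 100 nM or to the vehicle alone (0 nM, DMSO) for 2, 6 or 24 h. Per the labels, cells grew in RPMI-1640 medium with 10% serum, were plated 24 h before the drug was added, and received a final DMSO share of 0.25%. Total RNA was purified on Qiagen RNeasy columns and labelled with biotin using the Affymetrix HT one-cycle kit, per the labels' protocols. The line, dose and time of each array came from its title, and its tissue of origin from the tissue label. The labels gave 1 array per line, dose and time, so a cell line was the unit of replication, and nothing stated whether the 3 doses of a line came from separate cultures. P-values of the main gene tests therefore measured how within-line differences varied between lines, and the number of lines limited the precision.

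The deposited table held 22277 probe sets on the log2 scale, per the range of its values (2.75 to 14.4), with array medians between 4.69 and 5.07. The tool and method by which the authors computed these log2 values are not given in the sources used here, and no step was undone or added before the main tests. Probe sets were named through the platform annotation: 19070 carried 1 gene symbol, 1043 carried several and 2164 had none listed. Of the 19070, 19058 were matched to a current gene record through their Entrez number, and 0 symbols needed updating. The probe set with the highest mean over all arrays stood for its gene, which gave 11963 genes, 4310 of them with more than 1 probe set. Probe sets with several or no symbols were left out of the gene tests. No array had values identical to another (0 of 507), and the highest correlation between any 2 arrays was 0.998.

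Each dose was compared with vehicle within a time by limma (version 3.58.1 in R 4.3.3; lmFit and eBayes), with the 3 doses in 1 fit and the cell line as a block. The pairing came from the titles, since vehicle, 10 nM and 100 nM arrays of a line at a time came from 1 line, and the correlation between such arrays had a median of 0.952. The difference between 100 and 10 nM was a contrast of the same fit. Differences between times were tested on within-line differences from vehicle with the line as a block, vehicle arrays were compared between times in the same way, and differences between tissues were tested by limma's moderated F test over tissues with at least 3 lines. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of genes below are from limma.

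The gene lists, fixed with the tests and the alternatives before the data were examined, numbered 34. A first set concerned metabolism, protein synthesis and proliferation: cholesterol synthesis and LDL uptake; fatty acid synthesis and desaturation; glycolysis; hypoxia response; pentose phosphate pathway; amino acid synthesis and transport (targets of the transcription factor ATF4); aminoacyl tRNA synthetases; ribosome biogenesis; cytosolic ribosomal proteins and other mRNAs with a terminal oligopyrimidine tract; MYC and its targets; purine and pyrimidine synthesis; G1/S and DNA replication; G2 and mitosis; D cyclins and CDK inhibitors; lysosome and autophagy; growth factor receptors and FOXO targets; and mTOR pathway components with the FKBPs. Others held oxidative phosphorylation, the mitochondrial ribosome, interferon-stimulated genes, p53 targets, endoplasmic reticulum chaperones, heat shock proteins, the proteasome, immediate early genes, ERK pathway targets, NF-kB and inflammatory genes, NRF2 targets and reference genes. Markers of stromal, blood, epithelial, melanocyte and endothelial cells completed the set. Lists were tested by camera in limma with its preset inter-gene correlation of 0.01, adjusted over the 34 lists. Camera with an estimated correlation and fry were the alternatives. The size of a shift was the mean over a list's measured members of the within-line difference, averaged over lines. Counts of members past the threshold are given over all 11963 genes and, where they differed, adjusted over the list alone.

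List shifts were compared between tissues by a permutation test of the F ratio, and between 6 and 24 h over lines by Pearson's r and Spearman's rho, with 100000 resamples, so that the smallest p was 1e-05. These permutation tests used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Data were read with the R package data.table (version 1.17.8).

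Named genes followed a rule. For 100 nM at 24 h these were the 12 largest rises and 12 largest falls past the threshold with the same sign in at least 60% of lines. For the other doses and times 8 were taken each way, between doses or times 4 each way, and between tissues the 6 smallest p. Up to 4 members of each list were named by adjusted p, and FKBP1A, MTOR, RPS6KB1, MYC, CCND1 and HMGCS1 always. Within-line counts ("higher in 51 of 56 lines") cover the lines with both arrays.

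The steps were tested on simulated data in which 200 of the 11963 genes were changed by known amounts. A change of 0.2 on the log2 scale was recovered in 98% of such genes at 100 nM, 24 h, 96% at 6 h and 100% at 2 h. A change of 0.1 was recovered in 42%, 34% and 42%. For the difference between 24 and 6 h at 100 nM the share at 0.2 was 62%, and for tissues a difference of 0.4 was recovered in 16%. Camera called the 1 list that had been shifted, by -0.1, and 0 of the others. The simulated noise was independent between genes, so this could not show whether correlation between members of a list gives false calls.

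The alternatives were an unpaired fit, 1 fit over all arrays, a fit of only the 2 groups compared, the mean of all probe sets of a gene, a filter on dim genes, centring each array on its median, quantile normalization, array weights, eBayes with trend and robust, a stricter count with a log2 change of at least 0.2, and leaving out lines of shared origin, lines without all 9 arrays or each tissue in turn. Chosen after seeing the data were leaving out 7 lines whose arrays did not match across times, arrays with high values of 2 quality measures, the 6 h arrays of SK-OV-3 or lines and times with a marker list shift above 1, and covariates for the 3' to 5' difference of ACTB and for the hybridization controls. In 100 random splits per comparison, the labels were reassigned within lines, or among lines for tissues. Genes of the Y chromosome and XIST were not reported.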

Results

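Sirolimus (rapamycin) binds the immunophilin FKBP12, the product of FKBP1A, and the complex inhibits mTORC1, the kinase complex that couples growth factors and nutrients to protein synthesis. The series was designed to follow transcription over time after drug exposure across the NCI-60 panel, a set of established tumour cell lines. Gene expression was measured on oligonucleotide arrays in 59 lines from breast (6 lines), central nervous system (6), colon (7), leukemia (5), lung (9), melanoma (9), ovary (7), prostate (2) and kidney (8). Vehicle arrays numbered 56 at 2 h, 53 at 6 h and 58 at 24 h; arrays at 10 nM numbered 58, 54 and 58, and those at 100 nM 57, 56 and 57. All 9 arrays were present for 49 lines. The number of arrays limited the precision of each comparison.

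Arrays that carried the same line name matched each other across times in 52 lines, with correlations to the line's own arrays at other times of 0.816 to 0.961 (median 0.907 over 155 combinations of line and time). In 7 lines (A549, CCRF-CEM, HL-60, HS-578T, MOLT-4, RPMI-8226 and UACC-257, 47 arrays), arrays at some time were closer to another line than to their own name. Blood cell markers such as PTPRC, CD53 and LCP1 had a mean log2 level of 9.87, 8.67 and 10.3 at 2, 6 and 24 h in arrays labelled A549, a lung line. In arrays labelled with the leukemia line HL-60 the level was 5.14 at 2 h, 9.94 at 6 h and 9.76 at 24 h, and for MOLT-4 it was 4.82, 10.2 and 10.0. Arrays labelled K-562, also a leukemia line, matched each other across times but had levels of 4.22, 4.37 and 4.41, and the highest matched line of a solid tumour, the ovarian line OVCAR-8, had 6.67 at 24 h. The line closest to K-562 was NCI-ADR-RES, labelled ovarian, at each time (0.767, 0.701 and 0.702 at 2, 6 and 24 h), below the lowest own value of matched lines, 0.816. NCI-ADR-RES is known to share its origin with OVCAR-8, whose arrays were closest to another line at 0.456 or less. These values put the labels of K-562 and OVCAR-8 in doubt. Agreement across times cannot show a label that is wrong at all times, so whether the labels of K-562, NCI-ADR-RES and OVCAR-8 are right was not settled. Within a time, vehicle and drug arrays of the 7 lines correlated at 0.917 or more, against a median of 0.952 over all lines. Some matched lines lay lower, with 0.81 in MDA-MB-231 at 6 h, 0.868 in K-562 at 6 h and 0.87 in KM12 at 2 h. Stromal markers shifted by -1.60 at 100 nM in MDA-MB-231 at 6 h, and melanocyte markers by 2.68 at 10 nM in KM12, a colon line, at 2 h. Names and tissues below are therefore those of the labels, and counts without the 7 lines are given for some of the comparisons.

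**Figure D1:**
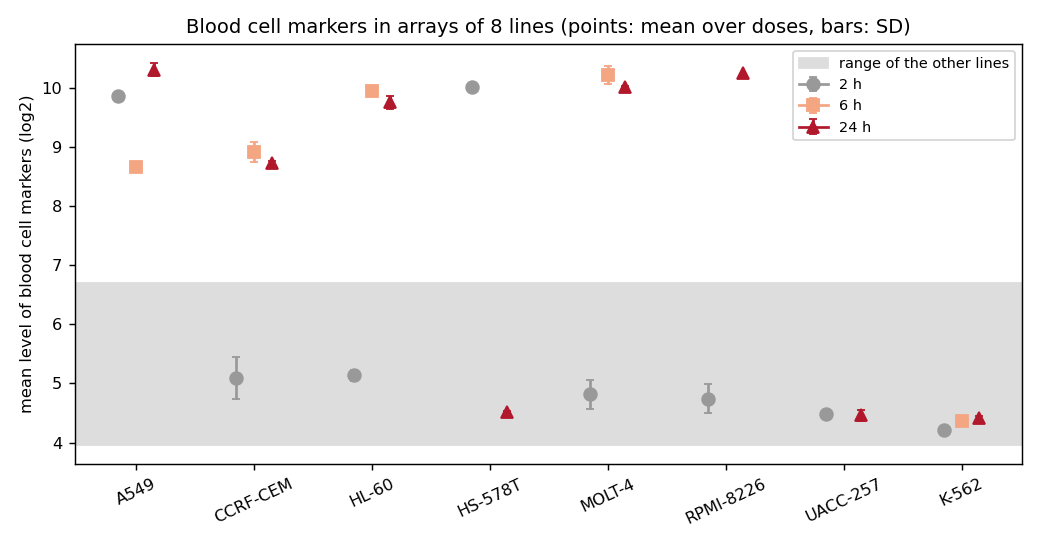
Mean log2 level of the blood cell marker list (vertical axis) in arrays of 8 lines, by time; points are means over doses, bars are SDs and the grey band is the range of the other lines. Arrays labelled A549 sat at 9.87 or 10.3 at 2 and 24 h, while those labelled K-562 stayed at 4.41 or below.

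Vehicle arrays gave the change in culture without the drug in matched lines. Arrays labelled HL-60 and MOLT-4 at 2 h correlated with their own names at other times at -0.192 and -0.127 (means). Pairs of such unmatched lines may therefore compare different cells rather than times. The estimates and list shifts of vehicle arrays below include these pairs, and their part in each value was not separated. From 2 to 24 h, the stress and early response genes ATF3, CCN1, CCN2 and MAFF fell by 1.17 (SE 0.096), 1.30 (SE 0.203), 1.28 (SE 0.189) and 1.01 (SE 0.190) on the log2 scale over 55 lines. DDIT4, a stress-induced inhibitor of mTORC1, rose by 0.84 (SE 0.125). ZNF322, PIK3R3 and RSBN1 rose by 0.71, 0.65 and 0.64. In all, 2467 of 11963 genes differed (1422 higher, 1045 lower), 3966 with array weights and 3669 without the 7 unmatched lines. Camera called 12 of the 34 lists, and 0 with an estimated correlation. Ribosome biogenesis genes fell (0 of 31 measured members rose and 21 fell, 26 fell adjusted over the list alone, mean shift -0.166, adjusted p = 2.10e-14, adjusted p = 0.138 with an estimated correlation). Immediate early genes, with DUSP1 at -0.97 and KLF4 at -0.59, fell as well (0 and 8 of 16, 10 fell adjusted over the list alone, shift -0.356, adjusted p = 4.65e-07, adjusted p = 0.138 with an estimated correlation). Respiratory chain genes rose (18 of 37, 1 fell, 20 and 2 adjusted over the list alone, shift 0.0888, adjusted p = 8.73e-10, adjusted p = 0.184 with an estimated correlation).

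Between 2 and 6 h, heat shock genes fell in vehicle arrays by 0.244 (SD 0.242, lower in 48 of 50 lines, 0 of 15 rose and 10 fell, likewise adjusted over the list alone, adjusted p = 3.41e-14, adjusted p = 0.0474 with an estimated correlation). CHORDC1 was at -0.75 and HSPH1 at -0.56. KLF11 fell by 0.95 (SE 0.108, lower in 49 of 50 lines), and RNF111, ZNF322, TOB2 and TUBD1 rose by 0.73, 0.67, 0.65 and 0.60. This comparison gave 2343 genes (1248 higher, 53.3%, 65.6% with each array centred on its median; 3630 genes with array weights) and 10 lists, 1 of them with an estimated correlation. From 6 to 24 h, 2983 genes differed (1518 higher, 1465 lower), led by FPGT (0.59), DZIP3 (0.58), IDH1 (0.55) and CDK19 (0.54) upward and by SPHK1 (-0.64), CXCL8 (-0.60) and MAFF (-0.57) downward. Camera called 12 lists here, and 0 with an estimated correlation. An unpaired fit without the cell line block called 141, 19 and 69 genes for 24 against 2 h, 24 against 6 h and 6 against 2 h.

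After 24 h at 100 nM, CCNG2, an atypical cyclin that accumulates in resting cells, rose by 0.88 (SE 0.084, higher in 51 of 56 lines, adjusted p = 1.08e-16) from a vehicle level of 7.12 (SD 0.994, n = 58). HBP1, a transcriptional repressor of cell cycle genes, rose by 0.88 (SE 0.0695, 52 of 56 lines), the small MAF protein MAFF by 0.92 (SE 0.0792, 51 lines, 1.89-fold), and MXI1, a MYC antagonist, by 0.68 (SE 0.0462, 53 lines). MCM10 and CDC6, which load and activate the replicative helicase, fell by 0.63 (SE 0.0637, lower in 51 of 56 lines) and 0.57 (SE 0.0643, 48 lines). HSPA14, an HSP70 chaperone, fell by 0.60 (SE 0.0394, 52 lines, adjusted p = 7.77e-26). MYC itself rose by 0.44 (SE 0.0459, 52 of 56 lines). Vehicle levels at 24 h were 7.99 for MAFF, 7.80 (SD 0.913) for MCM10, 9.01 (SD 0.626) for HSPA14 and 10.8 for MYC.

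Other large rises at 24 h were those of CCN2 (0.81), a matricellular protein, WDR45 (0.80), which acts in autophagy, TSPAN31 (0.70), SLC24A1 (0.67) and SPSB3 (0.67). They included GABARAPL1 (0.66), an ATG8 family member of the autophagosome, and TXNIP (0.65), which restrains glucose uptake. TRAPPC6A rose by 0.75 (SE 0.0650). Large falls were those of PDSS1 (-0.62), which makes the side chain of coenzyme Q, the hexokinase HK2 (-0.60), the purine salvage enzyme PNP (-0.59) and the serine synthesis enzyme PSAT1 (-0.58). Further falls were those of HSPA4L (-0.57), CCDC86 (-0.56), NOP16 (-0.56), the origin recognition factor ORC1 (-0.55) and ACAT2 (-0.54). FKBP1A rose by 0.13 (SE 0.0208, 46 of 56 lines) and CCND1 by 0.27 (SE 0.0488), while HMGCS1, an early enzyme of cholesterol synthesis, fell by 0.30. MTOR was at 0.04 (adjusted p = 0.329), and RPS6KB1, the S6 kinase gene, was at -0.09 (adjusted p = 0.0499).

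**Figure D2:**
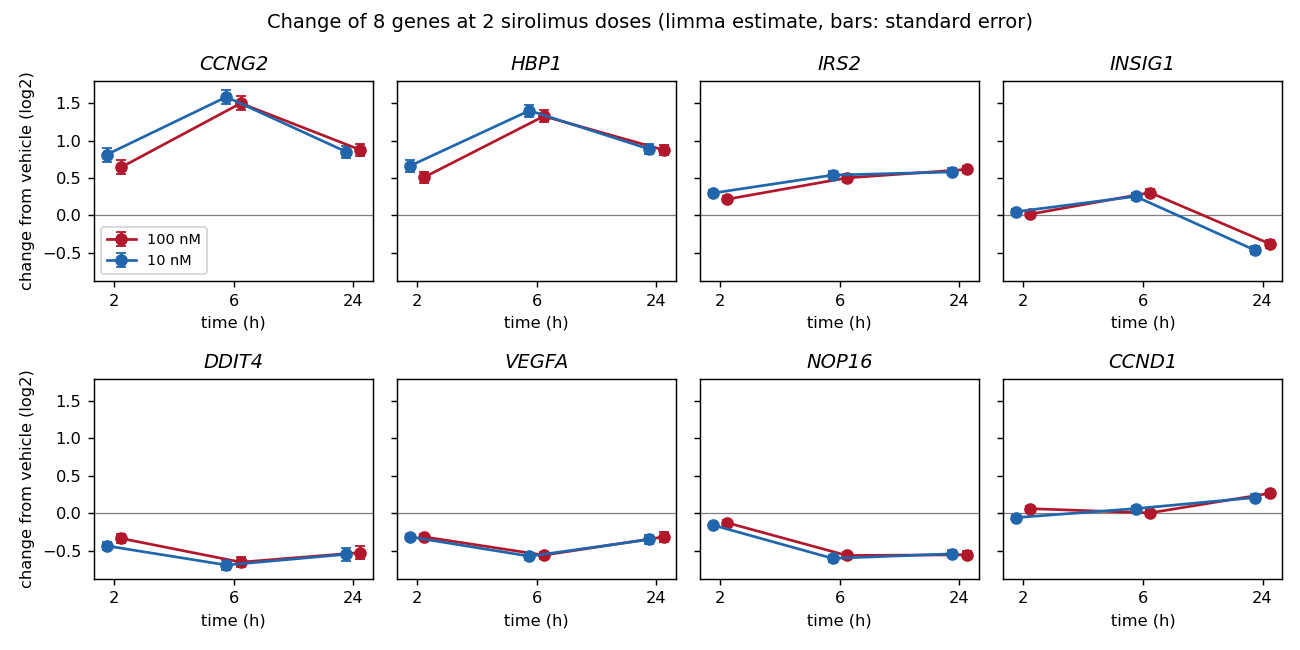
Change from vehicle on the log2 scale (vertical axis) of 8 genes at 2, 6 and 24 h (horizontal axis) at 10 and 100 nM; points are limma estimates and bars standard errors. CCNG2 reached 1.58 at 10 nM at 6 h, above its 0.81 at 2 h and 0.85 at 24 h.

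In all, 5113 of 11963 genes (42.7%) passed the threshold at 100 nM, 24 h, with 2414 higher (47.2%) and 2699 lower; 5796 had an unadjusted p under 0.05, where 598 would be expected by chance. With each array centred on its median the share of higher calls was 34.9%, and with quantile normalization 47.7%. A change of at least 0.2 was reached by 1679 genes. The unpaired fit without the cell line block called 86, and without the 7 unmatched lines 5267 genes passed. Of the 34 lists, 22 shifted, 8 upward, and 9 of them also with an estimated correlation; without the 7 unmatched lines 22 shifted.

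Genes that make ribosomes fell together at 24 h. Of 31 measured members of the ribosome biogenesis list, 0 rose and 30 fell, likewise adjusted over the list alone, with MRTO4 at -0.45, NOP2 at -0.41 and DDX21 at -0.41. The list shifted by -0.283 (SD 0.223, below 0 in 50 of 56 lines, adjusted p = 2.15e-18, adjusted p = 0.0251 with an estimated correlation). Mitochondrial ribosome genes fell (2 of 41 rose and 32 fell, likewise adjusted over the list alone, shift -0.159, SD 0.102, 49 lines, adjusted p = 1.02e-12, adjusted p = 0.0251 with an estimated correlation), led by MRPL39 at -0.39. Aminoacyl tRNA synthetases fell (0 and 14 of 16, likewise adjusted over the list alone, shift -0.213, SD 0.164, 48 lines, adjusted p = 1.05e-08). VARS1 was at -0.46 and YARS1 at -0.41. MYC targets fell (1 and 14 of 18, 2 and 14 adjusted over the list alone, shift -0.187, SD 0.148, 50 lines, adjusted p = 4.39e-08), NME1 among them at -0.39, although MYC rose. Genes of cytosolic ribosomal proteins, whose mRNAs are translated under mTORC1 control, went the other way (16 of 35 rose and 0 fell, 16 and 1 adjusted over the list alone, shift 0.0441, SD 0.0460, above 0 in 46 lines, adjusted p = 4.46e-05, adjusted p = 0.115 with an estimated correlation). RPL3 was at 0.19, and with each array centred on its median the mean of this list was smaller, though still above 0.

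Proteasome and heat shock genes were lower at 24 h. Of 28 proteasome subunit genes 1 rose and 25 fell (1 and 26 adjusted over the list alone), and the list shifted by -0.157 (SD 0.0858, below 0 in 54 of 56 lines, adjusted p = 7.77e-15, adjusted p = 0.0146 with an estimated correlation). PSMD11 fell by 0.34, in 55 of 56 lines, and PSMD12 by 0.33. Heat shock genes fell (0 and 14 of 15, 0 and 15 adjusted over the list alone, shift -0.268, SD 0.183, 50 lines, adjusted p = 1.07e-10, adjusted p = 0.0226 with an estimated correlation). Endoplasmic reticulum chaperones did not pass as a list (4 of 18 rose and 9 fell, adjusted p = 0.315); DNAJB9 rose by 0.55 and SDF2L1 fell by 0.53.

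Cell cycle genes fell in most lines at 24 h, with a wide spread. For G1/S and DNA replication, 1 of 36 rose and 30 fell, likewise adjusted over the list alone, and the shift was -0.250 (SD 0.290, 46 of 56 lines, adjusted p = 5.12e-12, adjusted p = 0.115 with an estimated correlation). CDC25A was at -0.45 and RFC5 at -0.44. G2 and mitosis genes fell (0 and 27 of 31, likewise adjusted over the list alone, shift -0.264, SD 0.354, 44 lines, adjusted p = 7.15e-12, adjusted p = 0.174 with an estimated correlation). CDC20 was at -0.44, AURKA at -0.42 and CCNB1 at -0.38. D cyclins and CDK inhibitors rose as a list (5 and 1 of 11, likewise adjusted over the list alone, shift 0.189, SD 0.161, 50 lines, adjusted p = 0.0203, adjusted p = 0.0626 with an estimated correlation). The CDK inhibitor gene CDKN1C rose by 0.64 and RBL2, a pocket protein of resting cells, by 0.42, while CCND3 fell by 0.37. The largest rise in this list was that of CCNG2, at 0.88, which is also a member of the growth factor receptors and FOXO targets.

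Several lists of metabolic genes fell at 24 h. Glycolysis genes shifted by -0.160 (SD 0.122, 49 of 56 lines, 1 of 20 rose and 15 fell, 1 and 16 adjusted over the list alone, adjusted p = 1.42e-07), with LDHA and PGAM1 at -0.26. Purine and pyrimidine synthesis shifted by -0.191 (SD 0.168, 49 lines, 0 and 14 of 18, likewise adjusted over the list alone, adjusted p = 1.58e-07, adjusted p = 0.0472 with an estimated correlation). PPAT was at -0.40 and UMPS at -0.33. Cholesterol synthesis genes fell (2 and 15 of 18, likewise adjusted over the list alone, shift -0.199, SD 0.217, 49 lines, adjusted p = 7.51e-06, adjusted p = 0.115 with an estimated correlation). DHCR7 was at -0.44 and IDI1 at -0.35. Fatty acid synthesis genes fell (0 and 11 of 12, likewise adjusted over the list alone, shift -0.229, SD 0.206, 48 lines, adjusted p = 1.89e-05, adjusted p = 0.0603 with an estimated correlation). SCD was at -0.43 and FASN at -0.41. ATF4 targets for amino acid supply fell (0 and 14 of 25, likewise adjusted over the list alone, shift -0.160, SD 0.261, 45 lines, adjusted p = 0.000175, adjusted p = 0.196 with an estimated correlation), SHMT2 by 0.32. Respiratory chain genes moved both ways (9 rose and 18 fell of 37, 10 and 18 adjusted over the list alone, shift -0.0426, SD 0.0634, 43 lines, adjusted p = 0.0274, adjusted p = 0.449 with an estimated correlation). NDUFS3 was at -0.25.

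Growth factor receptors and FOXO targets, which insulin and growth factor signalling represses, rose in 53 of 56 lines at 24 h (18 of 26 rose and 1 fell, likewise adjusted over the list alone, shift 0.254, SD 0.145, adjusted p = 2.56e-08, adjusted p = 0.00823 with an estimated correlation). The insulin receptor substrate gene IRS2 rose by 0.61, in 54 of 56 lines, and the receptor gene IGF1R by 0.46. Lysosome and autophagy genes rose (18 and 6 of 32, likewise adjusted over the list alone, shift 0.159, SD 0.137, 48 lines, adjusted p = 5.80e-06, adjusted p = 0.0603 with an estimated correlation), with the lysosomal proteases TPP1 at 0.45 and CTSB at 0.34. Smaller rises came from immediate early genes (9 and 1 of 16, adjusted p = 0.00809, adjusted p = 0.109 with an estimated correlation), DUSP1 among them at 0.41. ERK pathway targets rose (7 and 0 of 13, adjusted p = 0.0183, adjusted p = 0.221 with an estimated correlation). DUSP6 was at 0.46. Interferon-stimulated genes rose (15 and 1 of 28, shift 0.113, SD 0.212, adjusted p = 0.000884, adjusted p = 0.221 with an estimated correlation). IFI6 was at 0.26 and HLA-B at 0.25. Stromal markers rose (8 and 0 of 13, shift 0.278, SD 0.350, adjusted p = 0.00163, adjusted p = 0.115 with an estimated correlation). CCN1 was at 0.46 and TAGLN at 0.32. These last 4 counts were unchanged adjusted over the list alone.

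Several lists that did not pass at 24 h held members that moved in opposite directions. In the hypoxia response (5 rose and 8 fell of 21, adjusted p = 0.783), BNIP3L rose by 0.50 and HK2 fell by 0.60. Among mTOR pathway components and FKBPs (10 and 7 of 21, 10 and 8 adjusted over the list alone, adjusted p = 0.675), the autophagy kinase gene ULK1 rose by 0.38, and DDIT4 and FKBP4 fell by 0.53 and 0.40; the mean of the members was below 0 and their median above. The p53 targets (4 and 3 of 18, adjusted p = 0.675) and the pentose phosphate pathway (2 and 3 of 6, adjusted p = 0.968) did not pass either. The same held for NF-kB and inflammatory genes (5 and 2 of 18, 4 and 2 adjusted over the list alone, adjusted p = 0.421) and NRF2 targets (2 and 4 of 13, adjusted p = 0.440). Blood (1 and 2 of 10, adjusted p = 0.576), epithelial (3 and 0 of 10, 0.145), melanocyte (3 and 0 of 6, 0.295) and endothelial markers (0 and 1 of 6, 0.675) did not pass, nor did reference genes (1 and 3 of 7, 1 and 4 adjusted over the list alone, 0.432). B2M was at 0.12 and TBP at -0.14. Markers shifted far in single lines at 100 nM: melanocyte markers by 3.40 in SW-620, a colon line (4.06 at 10 nM), and by -2.07 in A498, a renal line (-2.01 at 10 nM). Epithelial markers shifted by 2.65 in the melanoma line SK-MEL-5, and stromal markers by 1.67 in MDA-MB-468 (1.62 at 10 nM), -1.04 in OVCAR-3 and 1.01 in DU-145. Without the lines and times in which a marker list shifted by more than 1 at either dose, 4964 genes and 22 lists passed at 100 nM, 24 h.

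**Figure D3:**
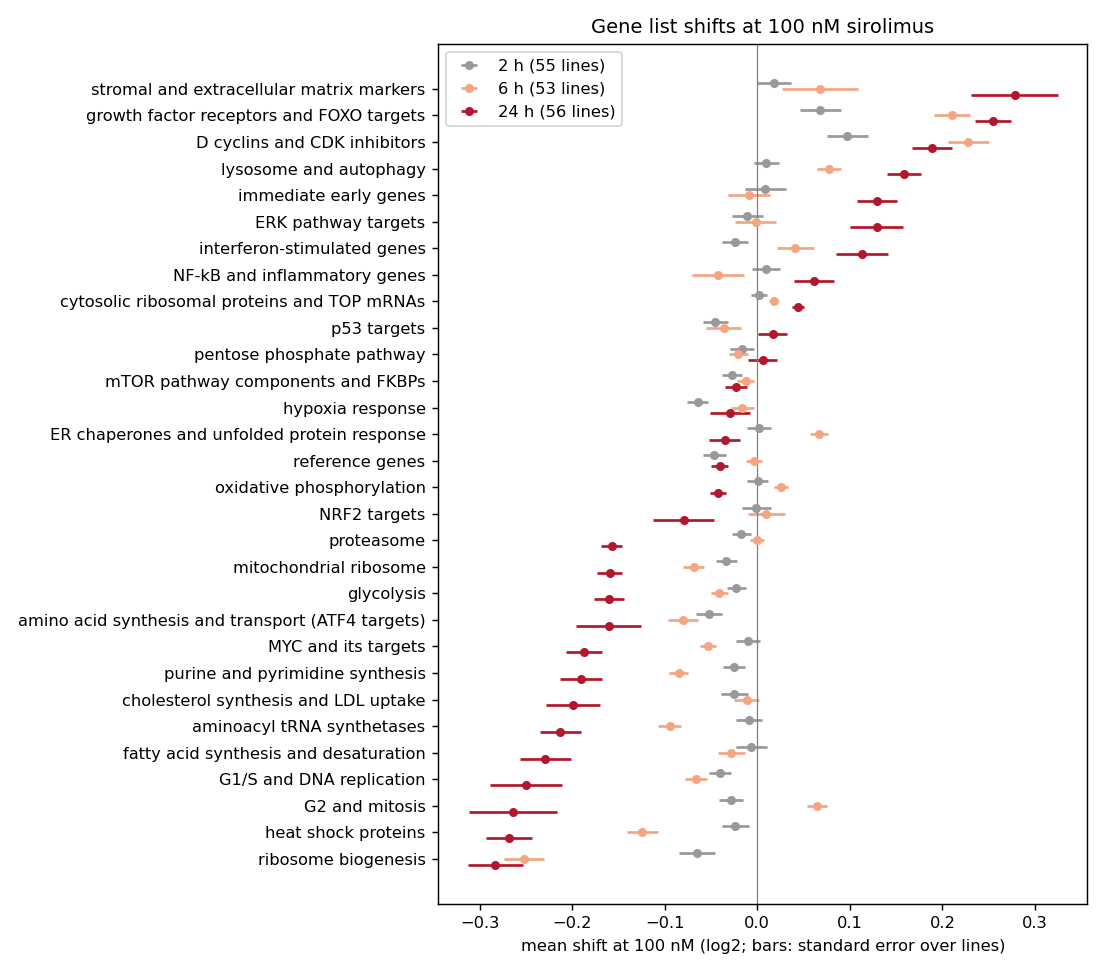
Mean shift of the gene lists, other than blood, epithelial, melanocyte and endothelial markers, at 100 nM against vehicle (horizontal axis, log2) at the 3 times; bars are standard errors over lines. Ribosome biogenesis lay at -0.283 at 24 h and -0.252 at 6 h, and growth factor receptors and FOXO targets at 0.254 and 0.210.

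At 6 h and 100 nM, CCNG2 and HBP1 had the largest rises. CCNG2 rose 2.83-fold (SE 0.0909 on the log2 scale, higher in 50 of 53 lines, adjusted p = 6.20e-28) from a vehicle level of 6.69 (SD 0.996, n = 53), and HBP1 by 1.33 (SE 0.0813, 50 lines). The MAX partner and MYC antagonist MNT rose by 0.82 (SE 0.0516, 51 lines), and FRAT2, a binding partner of GSK3, by 0.87 (SE 0.0588, 49 lines). DDIT4 fell by 0.66 (SE 0.0625, lower in 49 of 53 lines), the angiogenic factor VEGFA by 0.56 (SE 0.0486, 50 lines), and the nucleolar methyltransferase gene NOP2 by 0.59 (SE 0.0354, 50 lines). MYC was 0.17 above vehicle (SE 0.0302). Vehicle levels at 6 h were 7.59 (SD 1.67) for DDIT4 and 8.73 (SD 0.823) for NOP2.

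HECA and CCDC28A rose by 0.84 at 6 h, MAFF by 0.80 and RNF44 by 0.76. JMJD6, a hydroxylase of splicing factors, fell by 0.60 (SE 0.0367), NOP16 by 0.57, EDRF1 by 0.55, POP1, a subunit of RNase P, by 0.53 and HK2 by 0.52. FKBP1A rose by 0.08 and RPS6KB1 and HMGCS1 fell by 0.14 and 0.13, while CCND1 was at 0.00 (adjusted p = 0.961) and MTOR at 0.02 (adjusted p = 0.781). The threshold was passed by 3289 genes (27.5%), 1345 higher (40.9%) and 1944 lower, with 4261 at an unadjusted p under 0.05; 658 changed by at least 0.2, and the unpaired fit without the cell line block called 44.

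Ribosome biogenesis genes had already fallen at 6 h (0 rose and 28 fell of 31, likewise adjusted over the list alone, shift -0.252, SD 0.157, 49 of 53 lines, adjusted p = 3.05e-28, adjusted p = 0.00184 with an estimated correlation). RRS1 was at -0.49 and BYSL at -0.39. Growth factor receptors and FOXO targets rose (14 and 2 of 26, 15 and 2 adjusted over the list alone, shift 0.210, SD 0.141, 49 lines, adjusted p = 1.62e-08, adjusted p = 0.00184 with an estimated correlation). IRS2 was at 0.50 and FOXO3 at 0.39. D cyclins and CDK inhibitors rose (6 and 1 of 11, likewise adjusted over the list alone, shift 0.228, SD 0.161, 51 lines, adjusted p = 0.000688, adjusted p = 0.0118 with an estimated correlation), CDKN1B and CDKN1C each by 0.44. G2 and mitosis genes rose slightly, unlike at 24 h (15 and 3 of 31, likewise adjusted over the list alone, shift 0.0647, SD 0.0766, 45 lines, adjusted p = 4.27e-05, adjusted p = 0.21 with an estimated correlation). CDC25C was at 0.45 and CENPF at 0.33. These were 4 of 14 lists past the threshold at 6 h, of which 3 passed with an estimated correlation.

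The remaining 10 lists shifted by less than 0.13 at 6 h, and none passed with an estimated correlation. Falls came from tRNA synthetases (0 and 10 of 16, shift -0.0947, adjusted p = 0.129 with an estimated correlation) and heat shock genes (0 and 9 of 15, -0.124, adjusted p = 0.207 with an estimated correlation), DNAJB1 among them at -0.43. Purine and pyrimidine synthesis fell (1 and 7 of 18, -0.0848, adjusted p = 0.267 with an estimated correlation), PPAT by 0.43, and so did ATF4 targets (1 and 10 of 25, -0.0801, adjusted p = 0.267 with an estimated correlation) and ATF4 itself, at -0.21. The mitochondrial ribosome (2 and 20 of 41, 3 and 23 adjusted over the list alone, -0.0689, adjusted p = 0.267 with an estimated correlation) and G1/S genes (6 and 16 of 36, 6 and 17 adjusted over the list alone, -0.0659, adjusted p = 0.467 with an estimated correlation) fell too. Lysosome and autophagy genes rose (15 and 2 of 32, 17 and 2 adjusted over the list alone, 0.0774, adjusted p = 0.129 with an estimated correlation), with GABARAPL1 at 0.53 and ULK1 at 0.41. Endoplasmic reticulum chaperones rose (6 and 1 of 18, 7 and 1 adjusted over the list alone, 0.0665, adjusted p = 0.21 with an estimated correlation). DNAJB9 was at 0.70. Respiratory chain genes (17 and 1 of 37, 17 and 2 adjusted over the list alone, 0.0254, adjusted p = 0.33 with an estimated correlation) and cytosolic ribosomal protein genes (5 and 0 of 35, 0.0179, adjusted p = 0.427 with an estimated correlation) rose least. Where no second count is given, the count was the same adjusted over the list alone.

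After 2 h at 100 nM the same 2 genes had the largest rises. CCNG2 rose by 0.64 (SE 0.0938, higher in 45 of 55 lines, adjusted p = 1.11e-07), HBP1 by 0.51 (SE 0.0746, 46 lines), and KLF6, a zinc finger transcription factor, by 0.45 (SE 0.0518, 45 lines). FRAT2 (0.46), the kinase gene PIM1 (0.42), DNAJB9 (0.39), PNRC1 (0.39) and TGIF1 (0.29) rose as well. DDIT4 fell by 0.34 (SE 0.0559, lower in 41 of 55 lines) and VEGFA by 0.32 (SE 0.0405, 47 lines). The zinc exporter gene SLC30A1 (-0.33), SERTAD3 (-0.33), URB2 (-0.32), AUNIP (-0.29), TOB2 (-0.28) and SOCS5 (-0.27) were also lower.

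MYC was 0.16 higher at 2 h (SE 0.0369) and HMGCS1 0.13 lower on the log2 scale (-0.13, SE 0.0335), while CCND1 (0.06, adjusted p = 0.346), MTOR (0.05, 0.386), FKBP1A (0.01, 0.713) and RPS6KB1 (-0.10, 0.131) did not pass. Of 1306 genes past the threshold (10.9%), 292 were higher (22.4%) and 1014 lower, with 2946 at an unadjusted p under 0.05. The balance of rises and falls depended on the scaling: 66.0% of calls were higher with each array centred on its median and 38.7% with quantile normalization. Only 71 genes changed by at least 0.2, and the unpaired fit without the cell line block called 0, with limma. Without the 7 unmatched lines 1570 genes passed, and without the colon lines 826.

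Camera called 6 lists at 2 h, 0 of them with an estimated correlation, whereas fry, which tests whether members move one way, called 11. Ribosome biogenesis genes fell (0 and 11 of 31, 15 fell adjusted over the list alone, shift -0.0648, SD 0.143, 45 of 55 lines, adjusted p = 6.16e-06, adjusted p = 0.484 with an estimated correlation). POLR1C was at -0.26 and RRS1 at -0.18. Growth factor receptors and FOXO targets rose (5 and 1 of 26, 7 and 2 adjusted over the list alone, shift 0.0680, 42 lines, adjusted p = 0.00325, adjusted p = 0.484 with an estimated correlation). D cyclins and CDK inhibitors rose too (2 and 0 of 11, 4 and 0 adjusted over the list alone, shift 0.0973, 42 lines, adjusted p = 0.0153, adjusted p = 0.484 with an estimated correlation). Both of these lists hold CCNG2, at 0.64. The mitochondrial ribosome (0 and 10 of 41, 12 fell adjusted over the list alone, -0.0335, adjusted p = 0.00501, adjusted p = 0.686 with an estimated correlation) fell. So did ATF4 targets (0 and 6 of 25, 7 fell adjusted over the list alone, -0.0519, adjusted p = 0.0103, adjusted p = 0.484 with an estimated correlation) and G1/S genes (0 and 8 of 36, likewise adjusted over the list alone, -0.0404, adjusted p = 0.0153, adjusted p = 0.686 with an estimated correlation).

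The lower dose was 10 nM, at which CCNG2 and HBP1 were again among the largest rises at each time. At 2 h CCNG2 rose by 0.81 (SE 0.0932, higher in 51 of 56 lines) and HBP1 by 0.66 (SE 0.0741, 51 lines), with FRAT2 (0.58), PNRC1 (0.47), DNAJB9 (0.47), KLF6 (0.46), PIM1 (0.44) and FRAT1 (0.34). DDIT4 fell by 0.44, SLC30A1 by 0.36, in 54 of 56 lines, SERTAD3 by 0.35 and VEGFA by 0.32, TOB2 by 0.30, RPP38, another RNase P subunit, by 0.29, and ZNF200 and PCF11 by 0.28. At 6 h CCNG2 rose by 1.58 (SE 0.0909, 53 of 53 lines), HBP1 by 1.40 (52 lines), FRAT2 by 0.90, PIM1 by 0.88, MNT, MAFF and HECA by 0.85 and PNRC1 by 0.84. DDIT4 (-0.69), NOP16 (-0.60), EDRF1 (-0.60), NOP2 (-0.59), JMJD6 (-0.59), VEGFA (-0.58) and POP1 (-0.57) fell, and the ribosome assembly gene WDR3 fell by 0.56 and was lower in 53 of 53 lines.

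At 24 h and 10 nM, MAFF rose by 0.93 (SE 0.078, higher in 53 of 58 lines), HBP1 by 0.89, CCNG2 by 0.85, TRAPPC6A by 0.77, WDR45 by 0.75, CCN2 by 0.73, TXNIP by 0.70 and the autophagy receptor gene NBR1 by 0.67. PDSS1 fell by 0.61, HK2 by 0.60, PNP by 0.59, HSPA14 by 0.57, PSAT1, CCDC86 and ACAT2 by 0.56 and DDIT4 by 0.55. MYC was 0.16, 0.18 and 0.43 above vehicle at 2, 6 and 24 h, and HMGCS1 lay at -0.10, -0.18 and -0.39. FKBP1A was at 0.03 (adjusted p = 0.346), 0.09 and 0.10, and CCND1 at -0.06 (adjusted p = 0.443), 0.06 (adjusted p = 0.154) and 0.21. RPS6KB1 was at -0.10 (adjusted p = 0.167), -0.23 and -0.10, and MTOR did not pass (0.05, 0.03 and -0.04).

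The counts at 10 nM were 902 genes at 2 h (100 higher, 11.1%, and 802 lower, 57.9% higher with each array centred on its median, 26.6% with quantile normalization). They were 3737 at 6 h (1500 higher, 2237 lower) and 4756 at 24 h (2187 higher and 2569 lower, 35.2% higher with centring). The unpaired fit without the cell line block called 0, 63 and 82, with 2194 at an unadjusted p under 0.05 in the paired fit at 2 h. Camera called 9, 16 and 22 lists, and 0, 3 and 12 with an estimated correlation. The 3 at 6 h were ribosome biogenesis (0 and 29 of 31, 30 fell adjusted over the list alone, shift -0.267, SD 0.123), then growth factor receptors and FOXO targets (16 and 2 of 26, 17 and 2 adjusted over the list alone, 0.217, SD 0.119) and D cyclins and CDK inhibitors (4 and 1 of 11, 5 and 1 adjusted over the list alone, 0.226, SD 0.134). The last 2 of these lists both hold CCNG2, at 1.58 at 6 h. At 24 h the 22 lists were those called at 100 nM, with ribosome biogenesis at -0.280 (SD 0.187, below 0 in 53 of 58 lines) and the proteasome at -0.143 (SD 0.0894, 56 lines).

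Between 100 and 10 nM, limma called 0 genes at 2 h, 0 at 6 h and 1 at 24 h, with 993, 1386 and 555 at an unadjusted p under 0.05, where 598 would be expected by chance. The gene was P4HA1, a collagen prolyl hydroxylase induced by hypoxia, named after its values were seen. It was 0.17 higher at 100 nM (SE 0.0349, 48 of 56 lines, adjusted p = 0.0241), since it fell by 0.18 at 10 nM and was at 0.00 at 100 nM. The call ended in several alternatives, with 0 genes without the colon, breast, CNS, lung, melanoma or renal lines. The 95% interval of the mean difference over lines lay within 0.2 on either side of 0 for 99.2%, 98.7% and 99.0% of genes. These intervals were taken gene by gene without adjustment and with the dose labels as deposited. They argue against larger mean differences in most genes, but do not exclude one for any given gene or line. Changes at the 2 doses correlated over genes at 0.792, 0.929 and 0.972 at 2, 6 and 24 h; genes are not independent replicates, and unchanged groups against the same vehicle arrays gave 0.515, 0.504 and 0.498 in simulation. The covariance was 0.00247, 0.0101 and 0.0184, against 0.000812, 0.000820 and 0.000926 in simulation. With the lines split into 29 and 30, the change at 100 nM in the first part and at 10 nM in the other correlated at 0.419, 0.818 and 0.876, and the reverse pairing at 0.485, 0.765 and 0.878. At 24 h 1965 genes rose at both doses (441 for independent lists) and 2287 fell (580), at 6 h 1006 (169) and 1684 (364), at 2 h 51 (2.44) and 587 (68.0), and 0 went opposite ways.

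As lists, 10 differed between the doses at 6 h by camera, 1 at 2 h and 2 at 24 h, all lost with an estimated correlation, and fry called 0. The differences were small: cholesterol synthesis genes lay 0.0392 higher at 100 nM at 6 h (adjusted p = 0.000282, adjusted p = 0.392 with an estimated correlation). The G1/S and the G2 and mitosis lists lay at -0.0205 and -0.0234 at 24 h (adjusted p = 0.0192, adjusted p = 0.912 with an estimated correlation).

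The test of the difference between times asked which responses grew or faded. From 6 to 24 h at 100 nM, the sterol regulator gene INSIG1 went from 0.31 to -0.38 (difference -0.67, SE 0.073, lower in 46 of 52 lines). TRAPPC6A (0.70, SE 0.084), the retinaldehyde dehydrogenase gene ALDH1A3 (0.70, SE 0.147), TTC17 (0.64, SE 0.053) and TSPAN31 (0.59, SE 0.061) gained. PSAT1 (-0.57), ACAT2 (-0.55) and SDF2L1 (-0.54) had lower changes at 24 than at 6 h. From 2 to 6 h CCNG2 gained 0.71 (SE 0.119, higher in 44 of 50 lines), HBP1 0.69, RNF44 0.64 and HECA 0.62. EDRF1 (-0.46), NOP2 (-0.45, SE 0.043, lower in 48 of 50 lines), the recombination gene RAD54B (-0.42) and POP1 (-0.42) had lower changes at 6 than at 2 h. From 2 to 24 h TRAPPC6A gained 0.80, WDR45 0.74, TSPAN31 0.69 and SLC24A1 0.66. HSPA4L (-0.59), PDSS1 (-0.58), HSPA14 (-0.55) and ACAT2 (-0.54) had lower changes at 24 than at 2 h.

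Most lists moved between 6 and 24 h: camera called 21, 3 of them with an estimated correlation. The proteasome list fell by 0.161 between these times (below 0 in 50 of 52 lines, adjusted p = 2.14e-23, adjusted p = 0.000424 with an estimated correlation). MYC targets fell by 0.141 (adjusted p = 0.0362 with an estimated correlation) and glycolysis by 0.123 (adjusted p = 0.0362 with an estimated correlation). G2 and mitosis genes had the largest difference, -0.322 (44 of 52 lines, adjusted p = 5.15e-25, adjusted p = 0.0551 with an estimated correlation). From 2 to 6 h 7 lists moved, 0 with an estimated correlation, led by ribosome biogenesis (-0.160, adjusted p = 1.18e-17, adjusted p = 0.098 with an estimated correlation) and G2 and mitosis (0.0866, adjusted p = 1.90e-07, adjusted p = 0.211 with an estimated correlation). From 2 to 24 h 21 moved, 10 with an estimated correlation.

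The counts at 100 nM were 3831 genes for 24 against 2 h (2087 higher), 3049 for 24 against 6 h (1603 higher) and 1358 for 6 against 2 h (707 higher). The share of higher calls was 54.5%, 52.6% and 52.1%, and 27.1%, 31.4% and 38.9% with each array centred on its median. At 10 nM the counts were 3254 (1737 higher), 2656 (1389 higher) and 1330 (589 higher), with shares of 53.4%, 52.3% and 44.3%, and 25.8%, 31.8% and 32.3% with centring. At this dose NBR1 gained 0.62 between 2 and 24 h, and SCD had a lower change (-0.58) at 24 than at 2 h. INSIG1 (-0.73) and CCNG2 (-0.67) had lower changes at 24 than at 6 h. Between 2 and 6 h MNT gained 0.63, and NOC3L had a lower change (-0.45) at 6 h.

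Lines were next compared by tissue of origin, at 24 h, in the 54 lines of the 8 tissues with at least 3 lines. Ribosome biogenesis genes fell in renal (-0.438 ± 0.0889, SD, n = 8), CNS (-0.414 ± 0.191, n = 6), breast (-0.379 ± 0.105, n = 5) and ovarian lines (-0.349 ± 0.247, n = 7, and -0.438 without OVCAR-8, which was at 0.185 and whose label was not settled). In lung lines the mean was -0.276 ± 0.208 (n = 9, A549 at 0.0038 among them), in colon lines -0.218 ± 0.0936 (n = 7) and in melanoma lines -0.199 ± 0.112 (n = 8). Over the 6 tissues with at least 6 lines the list did not pass (F = 2.69, permutation test, adjusted p = 0.173), nor did it without leukemia (adjusted p = 0.112), so these means were not separated. In the 4 lines labelled leukemia the mean was 0.209 ± 0.236, with 3 lines above 0 (HL-60, CCRF-CEM and MOLT-4) and K-562 at -0.107. In these 3 lines the 100 nM minus vehicle difference ran against the other lines' profile over all genes (r = -0.273, -0.241 and -0.132), and with its sign turned there the leukemia mean would be -0.262 ± 0.149. Whether their dose labels and the line label of K-562 are right was not settled. Blood cell markers at 24 h lay at 9.76, 8.74 and 10.0 in arrays labelled HL-60, CCRF-CEM and MOLT-4 and at 4.41 in K-562. The permutation test over tissues gave F = 7.21 and p = 5.00e-05 (adjusted p = 0.00136), and 15 of 34 lists differed. With the sign turned in these 3 lines and A549, 9 lists differed, and ribosome biogenesis (F = 2.23, adjusted p = 0.128) and heat shock genes (F = 1.81, adjusted p = 0.229) were not among them. These lines were picked because their change ran against the others, so turning it brings them closer by construction. The turned values show how far the results rest on these arrays and test no cause. Heat shock genes were above 0 in 4 of 4 leukemia lines (0.155 ± 0.0774, and -0.128 ± 0.127 with the same 3 lines turned) and lowest in CNS lines (-0.399 ± 0.0936, F = 6.38, permutation test, adjusted p = 0.00136).

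At 100 nM the 6 genes with the smallest p had means above 0 in lines labelled leukemia as deposited, and below 0 with the same 3 lines turned, although K-562, left as it was, was above 0 in each. Each gene was above 0 in 4 of 4 leukemia lines, so turning 3 of them lowers the mean by construction. NOC3L, a ribosome assembly factor, was at 0.63 ± 0.259 in leukemia lines, higher in 4 of 4 (-0.27 ± 0.707 turned), and at -0.52 in CNS lines (adjusted p = 3.01e-05, limma's moderated F test). PLS1, which encodes an actin bundling protein, was at 0.63 in leukemia (-0.38 turned) and -0.96 in melanoma lines (adjusted p = 3.01e-05). The nucleolar genes GTPBP4 (0.40 in leukemia, -0.32 turned, adjusted p = 0.00053) and RRS1 (0.47, -0.21 turned, adjusted p = 0.00063) also differed, with DNAJA1 (-0.36 turned) and NUFIP1 (-0.33 turned, both adjusted p = 0.00092). These p values are those of the labels as deposited. At 10 nM the smallest p was shared by CHL1, CTDSP1, INTS8, PLS1, THOC6 and TPCN1 (adjusted p = 0.0110). THOC6 and CTDSP1 were highest in renal lines (0.76 and 0.66), CHL1 in melanoma (0.67) and TPCN1 in ovarian lines (0.60), while INTS8 was lowest in CNS (-0.43) and PLS1 in melanoma lines (-0.82). INTS8 and PLS1 had means above 0 only in leukemia lines, at 0.13 and 0.30, each higher in 4 of 4. At 100 nM 620 genes differed between tissues, and 44 at 10 nM. At 100 nM the counts of genes and lists rested largely on the lines labelled leukemia: without them 19 genes and 0 lists differed. Endoplasmic reticulum chaperones were lost without leukemia as well. They passed over the 6 tissues with at least 6 lines, which leave out breast as well as leukemia (F = 4.86, permutation test, adjusted p = 0.0360). The mean of the chaperone list was -0.0077 in leukemia lines, between melanoma (-0.166) and CNS lines (0.0746). Without the 7 unmatched lines 15 genes and 0 lists differed, but this left only K-562 of the leukemia lines, too few for a tissue, so that it showed no separate part of the unmatched lines. The 44 genes at 10 nM became 20 without leukemia, 14 without the 7 unmatched lines, 13 without renal, 14 without colon and 18 without CNS lines. Array weights raised the counts to 1039 and 304, and with the 49 complete lines, only 2 of them labelled leukemia and so without that tissue, 1 and 0 genes and 2 lists remained past the threshold.

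**Figure D4:**
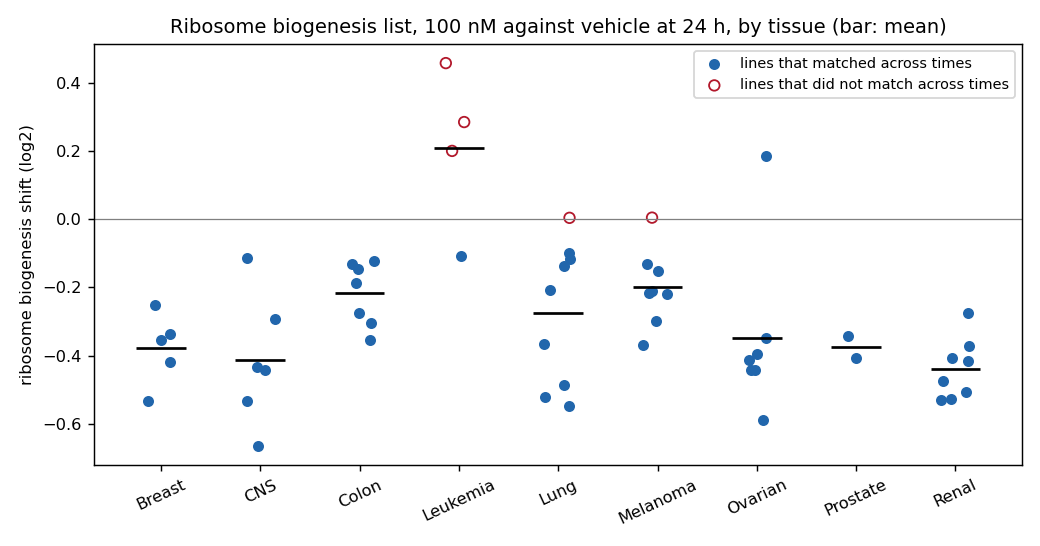
Shift of the ribosome biogenesis list at 100 nM against vehicle at 24 h (vertical axis, log2) in each line, by tissue label (horizontal axis); bars are means and open symbols are lines whose arrays did not match across times. Renal lines averaged -0.438, and lines labelled leukemia 0.209, with K-562 at -0.107.

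Whether the shifts of lines at 6 and 24 h went together was asked over the 52 lines with all 4 arrays at 0 and 100 nM. Shifts of G1/S and DNA replication genes at the 2 times correlated at r = 0.455 (permutation test, adjusted p = 0.0150, rho = 0.443, adjusted p = 0.0173), and at 0.432 without the 2 lines farthest from the median at 6 h. Immediate early genes gave r = 0.451 (adjusted p = 0.0150, rho = 0.530, adjusted p = 0.00306, r = 0.489 without the 2 lines). ERK pathway targets gave r = 0.385 (adjusted p = 0.0405, rho = 0.399, adjusted p = 0.0253, and 0.384 without the 2 lines). Growth factor receptors and FOXO targets gave r = 0.424 (adjusted p = 0.0238, rho = 0.294, adjusted p = 0.0987, and 0.5004 without the 2 lines). For ribosome biogenesis r was 0.257 (adjusted p = 0.220). By rank 6 lists passed, 3 of those above and also ATF4 targets (rho = 0.3997, adjusted p = 0.0253), D cyclins and CDK inhibitors (rho = 0.393, adjusted p = 0.0253) and the mitochondrial ribosome (rho = 0.363, adjusted p = 0.0455), for which r did not pass. The 4 lists of 34 that passed by r became 0 without the breast or without the renal lines and 8 without the ovarian lines. Fewer also passed without the colon, leukemia or lung lines and without the unmatched lines. Among the latter, arrays labelled A549 at 6 h correlated with that name's arrays at other times at only 0.328 (mean).

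**Figure D5:**
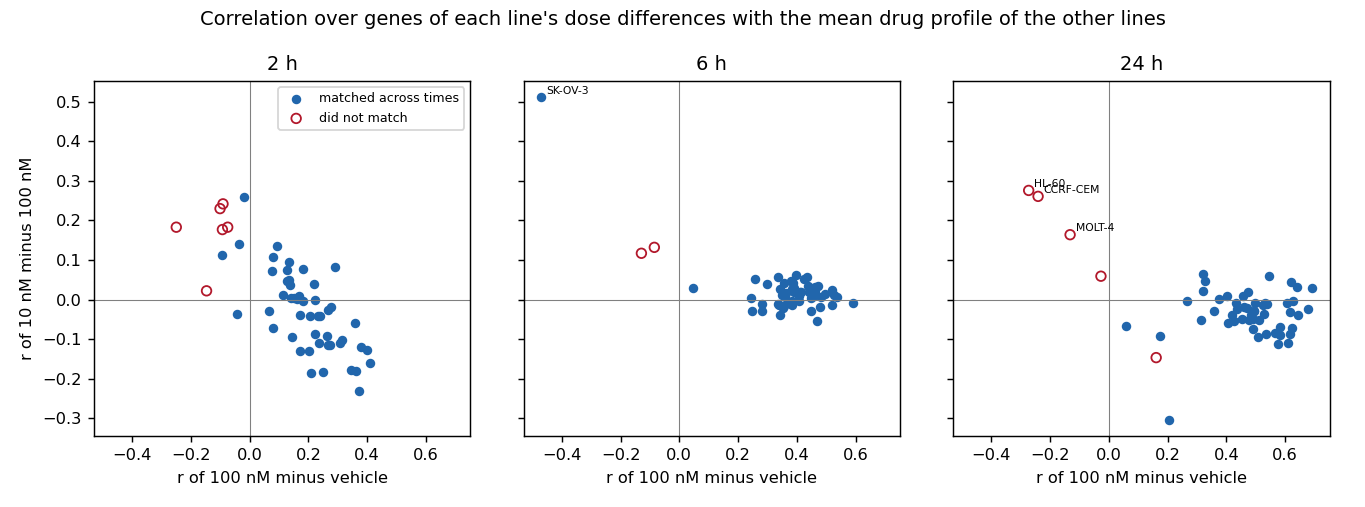
Correlation over genes of each line's 100 nM minus vehicle difference (horizontal axis) and 10 nM minus 100 nM difference (vertical axis) with the mean drug profile of the other lines, at each time; open symbols are lines whose arrays did not match across times. At 6 h SK-OV-3 lay at -0.472 and 0.512, and at 24 h HL-60 lay at -0.273 and 0.276.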

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

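The random splits and the tests of unmatched labels, exchanged dose labels and an opposite response were chosen after the results were seen, while those on G2 and mitosis genes, on the RNA quality of tissues and on A549 were written before.

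Arrays under 1 line name did not match across times in 7 lines. A change of the lines over time is argued against, since the highest correlation with another line's arrays, 0.97 between arrays labelled A549 at 2 h and HL-60 at 6 h, exceeded the highest own correlation of the matched lines, 0.961. A wrong label may account for it: of the 18 combinations of line and time in these lines, 16 correlated with another line at 0.816 or more, the lowest value of a matched line with itself. The lines were picked because they correlated better with another line than with their own name, so this count is no independent test. For HS-578T at 2 h a mixture of RNA stays open, since blood markers were at 10.0 and stromal markers lay 3.63 above those of the closest line (MOLT-4 at 6 h). No biological explanation other than the change over time was tested, and which label belongs to which culture was not worked out.

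G2 and mitosis genes were higher at 6 h (0.0647, SE 0.0105, 53 lines) and lower at 24 h (-0.264, SE 0.0474, 56 lines) at 100 nM. Of the technical explanations, RNA quality is argued against, as the shift at 6 h was 0.0639 with the 3' to 5' difference of ACTB held constant. Further scaling of the deposited values did not remove the shift, which was 0.0759 with median centring and 0.0681 with quantile normalization. The authors' own normalization is not known and was not undone, so its part could not be tested. Of the unmatched lines only A549 (0.0593) and MOLT-4 (0.0201) had both arrays at 6 h, and the shift was 0.0657 over the 51 lines left. Both lay below the mean, so they do not carry it, and leaving them out could not have lowered it. A response that changes sign between 6 and 24 h may be biological, which is a hypothesis found and tested on the same data, and the call at 6 h was lost with an estimated correlation (adjusted p = 0.21).

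List shifts at 100 nM, 24 h differed between tissues, with the mean of lines labelled leukemia above 0 and the means of the other tissues below for ribosome biogenesis and heat shock proteins. An opposite response over all genes at both doses is argued against in HL-60, CCRF-CEM, MOLT-4 and A549. Their 100 nM change ran against that of the other lines. Their 10 nM change had a median correlation of 0.021 with the other lines' profile, where an opposite response needs values well below 0. Single genes are not covered: at 10 nM the means of PLS1 (0.30) and INTS8 (0.13) were above 0 only in leukemia lines. CHL1, CTDSP1, THOC6 and TPCN1, also named at 10 nM, did not have this pattern. RNA quality is argued against as the whole cause, since 13 lists of the 15 still differed after the ACTB difference was fitted. Exchanged labels of vehicle and 100 nM arrays cannot be told apart from other causes: the 10 nM minus 100 nM difference lay above the 95th percentile of the other lines in 4 of these 4 lines, but it shares the 100 nM array by which they were picked. Whether A549 responded as its markers or as its label cannot be told apart, because its ribosome biogenesis shift of 0.0038 lay outside the other 8 lung lines (-0.548 to -0.0998) and also outside the 3 leukemia lines with high blood markers (0.2001 to 0.458), and a biological difference between tissues stays open and untested apart from these arrays.

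Tests of a difference between times picked out further results. At 100 nM the counts were 3831, 3049 and 1358 genes for 24 against 2 h, 24 against 6 h and 6 against 2 h, and at 10 nM 3254, 2656 and 1330. Between tissues they were 620 genes at 100 nM and 44 at 10 nM. From 6 to 24 h at 100 nM camera called 21 lists, of which only the proteasome, MYC targets and glycolysis passed with an estimated correlation, and the other 18 were lost (adjusted p = 0.0551 to 0.466 with an estimated correlation, 0.0551 for G2 and mitosis). The shifts of lists for growth differed by -0.0537 (ribosome biogenesis), -0.137 (tRNA synthetases), -0.141 (MYC targets), -0.117 (purine and pyrimidine synthesis), -0.101 (mitochondrial ribosome), -0.195 (G1/S) and -0.322 (G2 and mitosis). Metabolic lists differed by -0.200 (cholesterol synthesis), -0.212 (fatty acid synthesis), -0.123 (glycolysis), -0.0993 (ATF4 targets) and -0.0675 (oxidative phosphorylation). Lists of protein quality control differed by -0.161 (proteasome), -0.162 (heat shock proteins) and -0.0992 (endoplasmic reticulum chaperones). Differences above 0 were 0.0858 for lysosome and autophagy, 0.0756 for interferon-stimulated genes, 0.145 for immediate early genes, 0.149 for ERK pathway targets, 0.224 for stromal markers and 0.0285 for cytosolic ribosomal proteins, the last of which turned below 0 with median centring (fitted means of 0.0289 at 6 h and 0.0209 at 24 h).

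Among genes, the change at 100 nM differed between 24 and 6 h by 0.70 for TRAPPC6A, 0.70 for ALDH1A3, 0.64 for TTC17, 0.59 for TSPAN31, -0.54 for SDF2L1, -0.55 for ACAT2, -0.57 for PSAT1 and -0.67 for INSIG1. Between 6 and 2 h it differed by 0.71 for CCNG2, 0.69 for HBP1, 0.64 for RNF44, 0.62 for HECA, -0.42 for POP1, -0.42 for RAD54B, -0.45 for NOP2 and -0.46 for EDRF1.

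Between tissues at 100 nM, 24 h, adjusted p was 3.01e-05 for NOC3L and for PLS1, 0.00053 for GTPBP4, 0.00063 for RRS1 and 0.00092 for DNAJA1 and for NUFIP1. Of the lists, F was 7.21 for ribosome biogenesis, 6.38 for heat shock proteins, 5.81 for the mitochondrial ribosome, 5.54 for purine and pyrimidine synthesis, 4.62 for glycolysis, 4.42 for cytosolic ribosomal proteins, 4.24 for tRNA synthetases and 4.01 for MYC targets. It was 3.76 for the proteasome, 3.68 for endoplasmic reticulum chaperones, 3.51 for ATF4 targets, 3.25 for G1/S, 2.93 for lysosome and autophagy, 2.79 for the pentose phosphate pathway and 2.77 for fatty acid synthesis (54 lines in 8 tissues). These values rest on the labels as deposited: 0 lists passed without leukemia or without the 7 unmatched lines, which leaves out that tissue too (permutation test, against 15 at an adjusted p under 0.05 in all lines). With the sign turned in the 4 lines whose 100 nM change ran against the others, 9 passed, and F was 2.23 for ribosome biogenesis and 1.81 for heat shock proteins, neither of them past the threshold. Lines picked in this way move toward the others by construction when turned, so this tests no cause. Of genes, 19 differed without leukemia and 15 without the 7 unmatched lines.

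In 3 of 32 groups of lines of 1 tissue a line stood apart from the rest, where chance gives about 5%. These were OVCAR-8 among ovarian lines for ribosome biogenesis (0.185), K-562 among leukemia lines for the mitochondrial ribosome (-0.0579) and A549 among lung lines for the mitochondrial ribosome (0.103). Probe sets left out of the gene tests, with several or no symbols, also changed at 24 h, 883 of 3151 at 100 nM and 805 at 10 nM. Of 45 probe sets for bacterial and phage hybridization controls, 8 were higher at 100 nM, 2 h and 18 at 10 nM, 6 h, and limma called 0 in the other 4 comparisons of a dose with vehicle.

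Chance was tested with 100 splits per comparison, in which labels were reassigned within lines, or among lines for tissues. For 17 of the 20 comparisons 1 of 100 splits, the real one, gave as many genes. This is the smallest share that 100 splits can give, so chance is unlikely to account for these counts but is not excluded. The real counts and the highest of the other splits were 1306 and 34 (100 nM, 2 h), 902 and 1 (10 nM, 2 h), 3289 and 468 (100 nM, 6 h), 3737 and 266 (10 nM, 6 h), 5113 and 50 (100 nM, 24 h) and 4756 and 1356 (10 nM, 24 h). For differences between times at 100 nM they were 3831 and 2, 3049 and 5, and 1358 and 4, and at 10 nM 3254 and 936, 2656 and 2, and 1330 and 2, in the order 24 against 2 h, 24 against 6 h and 6 against 2 h. Between tissues they were 620 and 2 at 100 nM and 44 and 1 at 10 nM, and between vehicle arrays 2467 and 0, 2983 and 1, and 2343 and 1 in the same order of times. For 100 against 10 nM the count was 0 by limma at 2 h (highest other 4) and at 6 h (highest other 1), with 993 and 1386 at an unadjusted p under 0.05, so that 100 of 100 splits gave as many whatever the data and the test was void. At 24 h 2 of 100 splits gave as many as the 1 gene called (highest other 2).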

How the results depend on the processing

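The alternatives without the 7 unmatched lines, without arrays of high ACTB difference (11 arrays) or high residual (5 arrays), without SK-OV-3 at 6 h, without the 14 combinations of line and time in which a marker list shifted by more than 1, and with the ACTB or hybridization control covariates were chosen after seeing the data, and the others were planned. No named gene and no list shift against vehicle was past the threshold in both directions. With median centring the mitochondrial ribosome list at 10 nM, 2 h and the cytosolic ribosomal protein difference between 24 and 6 h crossed 0. For 955 results of named genes the alternatives gave 25461 values: 23746 stayed on the same side of the threshold, 306 were newly past it and 1409 no longer, 629 of these without the cell line block and 230 in 1 fit over all arrays. For 204 list results they gave 4482 values, of which 4277 stayed, 82 were newly past the threshold and 123 no longer, 62 of these with an estimated correlation. Signal over background was not measured, and the number of arrays limited precision. Where a count moved and its construction does not show why, the cause was not tested. An alternative for the pseudocount had no value, since the deposited values were already on the log scale.

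Without the cell line block, which leaves the spread between lines in the error, limma called 0 genes at 2 h at each dose, 44 (100 nM) and 63 (10 nM) at 6 h, 86 and 82 at 24 h, 0 between doses at 24 h, and 141, 19 and 69 between vehicle arrays (24 against 2 h, 24 against 6 h, 6 against 2 h). In 1 fit over all arrays with 9 groups it called 242 (100 nM) and 237 (10 nM) at 2 h, 1415 and 1800 at 6 h, and 0 between doses at 24 h.

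A log2 change of at least 0.2 was reached by 71 and 96 genes at 2 h (100 and 10 nM), 658 and 817 at 6 h, 1679 and 1541 at 24 h and 0 between doses at 24 h. For differences between times the counts at this limit were 1663, 1208 and 394 at 100 nM, 1298, 939 and 407 at 10 nM and 844, 953 and 629 in vehicle arrays (24 against 2 h, 24 against 6 h, 6 against 2 h), a smaller number by construction.

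Between 100 and 10 nM at 6 h, where 0 genes passed, the count was 4 in a fit of only the 2 groups compared, 35 with the mean of all probe sets, 3 with array weights, 2 without the marker shifts, and 1 without leukemia, without arrays of high ACTB difference or with the ACTB covariate. At 24 h, where 1 passed, it was 0 without arrays of high ACTB difference, without arrays of high residual, without MDA-MB-435, NCI-ADR-RES and SNB-19, and without breast, CNS, colon, lung, melanoma or renal lines. It was 2 in a fit of only the 2 groups compared, without leukemia, with complete lines and without the 7 unmatched lines, 4 with quantile normalization and 11 with array weights.

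At 100 nM, 2 h 826 genes passed without colon lines. Vehicle arrays with array weights gave 3966 genes for 24 against 2 h and 3630 for 6 against 2 h. Without the 7 unmatched lines 24 against 2 h gave 3669 vehicle genes.

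Genes that differed between tissues at 100 nM (620) numbered 19 without leukemia, 1039 with array weights, 1 with complete lines and 15 without the 7 unmatched lines. At 10 nM (44) they numbered 14 without colon, 20 without leukemia, 92 without breast, 18 without CNS, 22 without the marker shifts, 13 without renal and 78 without ovarian lines, 75 with the mean of all probe sets, 304 with array weights, 85 with quantile normalization, 0 with complete lines (by limma, against 1567 at an unadjusted p under 0.05 in all lines), 14 without the 7 unmatched lines and 27 with trend and robust.

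With an estimated correlation, camera called 0, 3 and 9 lists at 100 nM (2, 6 and 24 h) and 0, 3 and 12 at 10 nM. Fry called 11 at 100 nM, 2 h, and camera 5 at 10 nM, 2 h with quantile normalization. Lists that differed between tissues (15) numbered 0 without leukemia, 2 with complete lines, 0 without the 7 unmatched lines, 9 with the sign turned in 4 lines (chosen after seeing the data) and 1 over tissues with at least 6 lines. Lists correlated between 6 and 24 h (4) numbered 1 without colon, 1 without leukemia, 0 without breast, 0 without renal, 2 without lung and 8 without ovarian lines, 2 without the 7 unmatched lines and 7 without the 2 farthest lines.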

Other observations

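The tests of the 4 hypotheses below were written before their results were seen, while the counts of uniform genes, of opposite changes and of dose order were chosen after the main results were seen.

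Some genes moved the same way in nearly all lines at 100 nM. At 24 h 115 genes were higher and 140 lower in at least 90% of 56 lines, at 6 h 76 and 159 of 53 lines, and at 2 h 0 and 0 by this count, with 1306 genes called by limma and 2946 at an unadjusted p under 0.05. ATP6AP2, an accessory subunit of the vacuolar proton pump, rose by 0.27 in 55 of 56 lines, SPG11, which acts in lysosome renewal, by 0.41 in 55, HGSNAT, a lysosomal acetyltransferase, by 0.57 in 54, and AMOTL2 by 0.51 in 54. The falls included the mitochondrial ATP synthase gene ATP5MC1 (-0.46, lower in 54 of 56 lines), the nucleoporin gene NUP188 (-0.38, 54 lines), NUBP1 (-0.35, 54 lines), the spindle gene SPAG5 (-0.35, 54 lines) and the splicing gene DNAJC8 (-0.20, 55 lines).

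Of 2248 genes past the threshold at both 6 and 24 h, 216 had opposite signs. Higher at 6 h and lower at 24 h were 109 genes, 11 of them members of the G2 and mitosis list. INSIG1, a sterol sensor target, went from 0.31 (SE 0.0418) to -0.38 (SE 0.0530), the mitotic checkpoint kinase genes BUB1 from 0.09 to -0.42 and TTK from 0.26 to -0.19, KIF14 from 0.26 to -0.19 and CENPA from 0.18 to -0.26. Lower and then higher were 107 genes, such as TTC17 (-0.11 and 0.50), the mismatch repair gene PMS1 (-0.32 and 0.15) and SPATA2L (-0.34 and 0.10).

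A hypothesis was that lines with a higher vehicle level of interferon-stimulated genes at 2 and 6 h would rise further in that list at 24 h. Over 47 lines r was 0.401 (permutation p = 0.00738, adjusted p = 0.0295 over 4 hypotheses) and 0.470 without the 2 farthest lines, while rho was 0.293 (adjusted p = 0.180). A link between the 2 may exist by r and was not past the threshold by rho.

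The other 3 hypotheses were not past the threshold. For the vehicle level of ribosome biogenesis genes and their shift at 24 h r was 0.025 (permutation p = 0.863, rho = 0.0380, 47 lines, r = 0.0198 without the 2 farthest lines), and for the vehicle level of FKBP1A, the drug's binding partner, it was 0.139 (permutation p = 0.353, rho = 0.140, 47 lines, r = 0.137 without the 2 lines). For the fall of ribosome biogenesis genes at 6 h and that of G2 and mitosis genes at 24 h r was 0.040 (permutation p = 0.775, rho = 0.196, 50 lines). This r rested on few lines: it was 0.236 without the 2 farthest (permutation p = 0.107) and 0.248 without SK-OV-3 (permutation p = 0.0855, rho = 0.249, 49 lines), a value chosen after seeing the data. After adjustment over the 4 hypotheses p was 0.863, 0.705 and 0.863.

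Single lines had unusual values. In SK-OV-3 at 6 h the correlation with the other lines' profile was -0.472 for 100 nM minus vehicle, 0.050 for 10 nM minus vehicle and 0.512 for 10 minus 100 nM, against a median of 0.388 for the first, and CCNG2 was at -2.07 in its 100 nM minus vehicle difference. Whether the vehicle and 100 nM labels of that line are exchanged was not settled. At 24 h CCNG2 was at -1.21 in arrays labelled HL-60, -0.59 in MOLT-4, -0.79 in A549 and 0.82 in K-562. At 24 h HOP-92 had a correlation of 0.204 at 100 nM and -0.105 at 10 nM. At 2 h 10 of 55 lines had a correlation below 0 at 100 nM, where the median was 0.172. Arrays labelled HS-578T, a breast line, had MLANA at 12.8, TYR at 12.8 and PMEL at 13.5 at 24 h. They correlated at 0.947 with arrays labelled UACC-257, a melanoma line, and were counted as breast between tissues at 10 nM. Melanocyte markers were at 11.6 and 11.3 in arrays labelled UACC-257 at the 2 times measured, where matched melanoma lines reached 11.5. Stromal markers were at 12.6 in arrays labelled HL-60 at 2 h.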
